A study of Mus musculus with 16 samples.

How the data were processed

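The series holds 16 single-cell RNA libraries of liver cells of Pdcd1-/- mice, isolated with CD45 microbeads after enzymatic dissociation, 4 each from mice given isotype antibody with vehicle (called vehicle here), anti-CTLA4, epacadostat or both. The design text of the series also mentions an agonist of 4-1BB, and no such sample was analysed here. Per the submitters' processing notes, Cell Ranger 3.0.2 and Seurat 3.0.1 were used with the mouse genome mm10. The authors deposited for each sample a matrix of UMI counts per gene and barcode, with 31053 genes, not normalised. No barcode held fewer than 500 UMIs. Whether other filters were applied before deposit is not given in the sources used here. Gene coordinates are those of the annotation of GRCm38 used here.

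The matrices held 70198 barcodes, between 2693 and 6282 per sample. Barcodes with at least 200 genes, at least 500 UMIs and under 10% of UMIs from mitochondrial genes were kept. The mitochondrial limit removed 16241 barcodes, with a median of 989 UMIs. Of the 53142 that passed, 1929 (3.63%) were removed as doublets, those with the highest scores of scanpy's doublet caller at a rate of 0.8% per 1000 barcodes. The caller's own threshold had marked 59 (0.111%), too few to be useful, and was replaced for that reason. The 51213 remaining cells had 3836 to 7580 UMIs and 1467 to 2367 genes per cell (range of the samples' medians).

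Cells were clustered with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2 and igraph 0.11.9 in Python 3.11.15 (2000 variable genes, 30 principal components, 20 neighbours, resolution 1), which gave 43 clusters. The 11 clusters of T and NK cells (15640 cells) were clustered again at resolution 2 into 33 sub-clusters, leaving out 1040 genes whose correlation with a proliferation score was above 0.15. Clusters were named from markers fixed before the data were examined, as were the tests, the comparisons, the rule for named genes and 36 gene lists. A name needed at least 3 markers in at least 10% of cells and 1.5 times the level of other cells. These thresholds, the sub-cluster resolution and the rule for NK cells were set over several rounds after the clusters' markers and the samples' shares of clusters had been seen, and before any test of shares or genes. In all, 42788 cells were named, in 13 classes. Unnamed cells were 10.3% of cells with vehicle, 14.9% with anti-CTLA4, 9.50% with epacadostat and 8.86% in the combination group. T cells given neither the CD8 nor the CD4 name were 7.58%, 4.74%, 6.43% and 5.05% in the same order. They included sub-cluster 17, which failed the naming rule though 93.4% of its cells had Cd8b1 and 5.18% had Cd4. It held 1.32% of cells with vehicle and 0.610% in the combination group. Sub-cluster 14, with both genes frequent and led by Foxp3, a gene of regulatory T cells, held 0.204% and 1.87%. The CD8 share of T cells below leaves all of these cells out. Differences in depth between groups can move cells between named and unnamed clusters, and rebuilt names need not match those of the study.

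Shares of cells were compared by exact permutation, stratified by the other drug for the effect of each drug (4900 arrangements) and between 2 groups otherwise (70 arrangements), with Benjamini-Hochberg adjustment over classes. Raw counts were summed per sample and class, where a sample held at least 20 cells and a group at least 3 such samples, and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, all 16 samples in 1 fit per class, 1 mean per group). Adjusted p under 0.05 within a class counted as a call. CPM values are counts normalised by edgeR to the library size. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry. Of the 36 lists, 31 had at least 4 tested members in some class. The 29 list results discussed were chosen after the list results had been seen. Genes were named by rule: the 3 largest rises and 3 largest falls per class and comparison among called genes with at least 20 CPM in a group and no overlap between the groups' samples, up to 4 members of each list discussed, by smallest p, and Pdcd1, Ctla4, Ido1, Ido2 and Tdo2. Receptor segments of B and T cells, haemoglobin, mitochondrial and provisional gene names were left out. CD8 T-like, CD4 T-like, monocyte/macrophage-like and Kupffer-like cells were given in full. Plasmacytoid DC-like, mast/basophil-like, platelet-like and erythroid-like cells were too few to test.

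The tests were checked on simulated counts with 200 genes changed by known folds. These counts were drawn independently for each gene, with no shared difference between libraries other than depth. The rates below hold for that setting, and false calls from other differences shared by libraries are not covered. For the combination against vehicle in CD8 T-like cells, edgeR recovered 28.4%, 65.2% and 93.9% of genes changed 1.5-, 2- and 4-fold, with 1.59% of calls false. It recovered 22.4%, 60.0% and 98.5% in CD4 T-like cells (5.56% false), in monocyte/macrophage-like cells 35.8%, 74.6% and 93.8% (3.57% false), and in Kupffer-like cells 21.2%, 62.1% and 96.9% (5.6% false). A chi-square test of counts found no 2 samples of a group alike within sampling noise (lowest ratio to its degrees of freedom 13.8).

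Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a replicate block, doublets kept, a mitochondrial limit of 5%, finer clustering at 2 times the resolution, a fit of the 2 groups compared, leaving out each sample, another denominator for shares, limma on logit shares and edgeR on cell counts. Chosen after seeing the data were the fits without anti-CTLA4 replicate 4 and epacadostat replicate 3, which stood apart in quality values and first gene counts, the leaving out of samples for shares between 2 groups, and the term for the sides of the mitochondrial share. That term was added after counts, their values without single samples and deviations within groups had been seen, and it was the only such division tried. Vehicle replicate 2 was not among the doubted samples, though the counts for the combination against vehicle in the 4 classes given in full were highest without it. Other software was numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, statmod 1.5.0 and the R package for tables (data.table, version 1.17.8).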

Results

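Immune cells were isolated with CD45 microbeads from the livers of Pdcd1-/- mice, which lack PD-1, an inhibitory receptor of activated T cells. They were profiled by droplet-based single-cell RNA sequencing from the 5' end of transcripts. Mice received isotype antibody and vehicle as the control (called vehicle below), an antibody against CTLA-4, another inhibitory receptor of T cells, epacadostat, an inhibitor of the tryptophan-degrading enzyme IDO1, or anti-CTLA4 plus epacadostat, called the combination below. Each of the 4 groups held 4 samples, 16 in all. The title of the series places them in a study of T cells and monocyte-derived myeloid cells in hepatitis caused by immunotherapy. Total UMI counts ranged from 12907718 to 43459296 per sample. After filtering, 51213 cells remained, between 2094 and 4366 per sample, with a median of 3836 to 7580 UMIs per cell. The mean of the samples' median UMIs per cell was 4766 with vehicle, 5261 with anti-CTLA4, 5342 with epacadostat and 6942 in the combination group, so depth differed between groups. The labels number the samples of each group but do not say what a number shares, and p-values measure the spread between these samples.

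The median share of UMIs from mitochondrial genes fell into 2 ranges. In 10 samples it lay between 2.37% and 3.15%. These were all 4 combination samples, anti-CTLA4 replicates 1 to 3, epacadostat replicates 3 and 4, and vehicle replicate 2. In the other 6 samples (vehicle replicates 1, 3 and 4, epacadostat replicates 1 and 2, and anti-CTLA4 replicate 4) it lay between 3.96% and 4.59%. The gap was 0.803 percentage points wide, against 0.278 for the next widest. Because the sides overlap unevenly with the groups, values from a model with a term for the side, called the mitochondrial term below, are given beside the comparisons.

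**Figure D1:**
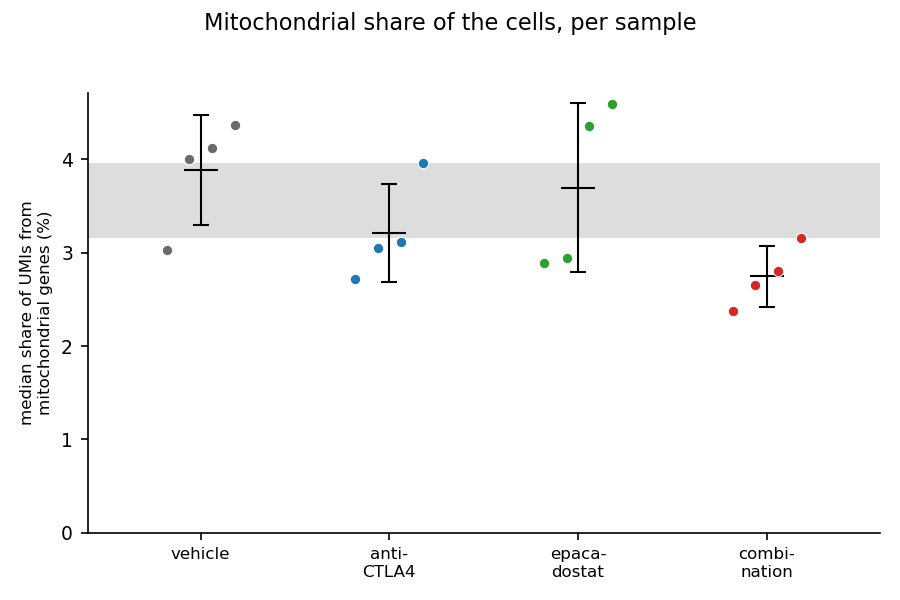
Median share of UMIs from mitochondrial genes (y axis, %) in each of the 16 samples by group (x axis), with the group mean (horizontal line) and SD (bars, n = 4). The grey band marks the widest gap, from 3.15% to 3.96%, with all 4 combination samples below it and 3 of 4 vehicle samples above it.

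Transcripts of the deleted gene and of the drug targets were examined first. Pdcd1 was detected in CD8 T-like cells of every group, with a mean of 217 ± 56.7 library-size-normalised counts (CPM; SD, n = 4) with vehicle, 245 ± 74.9 with anti-CTLA4, 159 ± 25.8 with epacadostat and 157 ± 30.6 in the combination group. Tags from the 5' end can lie outside a deleted part of the gene, and the part deleted is not given in the sources used here, so these counts do not check the genotype. Ctla4 in CD4 T-like cells averaged 352 ± 82.5 CPM with vehicle, 574 ± 270 with anti-CTLA4, 458 ± 44.9 with epacadostat and 491 ± 126 in the combination group, and its difference passed adjusted p 0.05 in no comparison (edgeR). Ido1, the target of epacadostat, gave 4 to 19 UMIs per sample over the cells summed for this count, which were not all of the cells kept. The related genes Ido2 (0 to 3 UMIs) and Tdo2 (3 to 23 UMIs) were as rare, so differences in these genes were not detectable at this depth.

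The first comparison asked which cell populations moved with each treatment. CD4 T-like cells rose with both. They made up 3.43% ± 0.785 of all cells with vehicle (SD, n = 4), 5.50% ± 0.584 with anti-CTLA4, 6.51% ± 0.793 with epacadostat and 9.26% ± 0.734 in the combination group. B-like cells fell with epacadostat, and made up 17.4% ± 3.74 with vehicle, 14.2% ± 4.95 with anti-CTLA4, 10.1% ± 3.17 with epacadostat and 7.42% ± 1.40 in the combination group. Monocyte/macrophage-like cells rose with anti-CTLA4, at 17.1% ± 3.69 with vehicle, 23.5% ± 9.20 with anti-CTLA4, 13.7% ± 1.85 with epacadostat and 28.7% ± 9.41 in the combination group. The CD8 share of T cells fell with anti-CTLA4, at 76.2% ± 10.5, 60.3% ± 8.80, 71.3% ± 8.42 and 62.4% ± 6.53 in the same order.

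Effects were averaged over the levels of the other drug and tested by exact stratified permutation (two-sided, 4900 arrangements, smallest possible p 0.000408), adjusted over 13 classes. Anti-CTLA4 raised CD4 T-like cells by 2.41 percentage points (exact test, adjusted p = 0.00531) and monocyte/macrophage-like cells by 10.7 points (adjusted p = 0.0451). The CD8 share of T cells changed by -12.4 points (exact test, p = 0.0151), but by -10.02 points without anti-CTLA4 replicate 4 and epacadostat replicate 3, which did not pass (exact p = 0.0571). Epacadostat raised CD4 T-like cells by 3.42 points and changed B-like cells by -7.03 points (exact test, both adjusted p = 0.00265). A rise of CD8 T-like cells with epacadostat (5.96 points, exact adjusted p = 0.113) and a lower share of NK/ILC1-like cells with anti-CTLA4 (-2.56 points, exact adjusted p = 0.0761) did not pass. Between 2 single groups the smallest exact p is 0.0286, and no share passed after adjustment. Adjusted over 13 classes that p can pass only if many classes reach it together, so this says little about single classes. For the combination against vehicle, limma on logit shares called CD4 T-like (log2 change 1.54, adjusted p = 0.000114) and B-like cells (-1.39, adjusted p = 0.00854). It called none for anti-CTLA4 against vehicle (lowest adjusted p = 0.0902). The interaction of the drugs passed for no class (limma on logit shares, lowest adjusted p = 0.830). Permuting within the mitochondrial sides left the epacadostat effects on CD4 T-like (3.46 points) and B-like cells (-5.64 points) past the threshold (exact test, both adjusted p = 0.00619). The anti-CTLA4 effect on CD4 T-like cells was 2.55 points there (exact adjusted p = 0.0542). This is the smallest adjusted p that the fewer arrangements within the sides allow for a single class, so the miss says nothing about stability. The anti-CTLA4 effect on monocyte/macrophage-like cells did not pass within the sides (8.69 points, exact adjusted p = 0.271). The monocyte/macrophage-like call was also lost without any 1 of 12 samples (exact adjusted p from 0.0504 to 0.149), and held only without anti-CTLA4 replicate 4, vehicle replicate 2 or combination replicate 2 or 3.

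**Figure D2:**
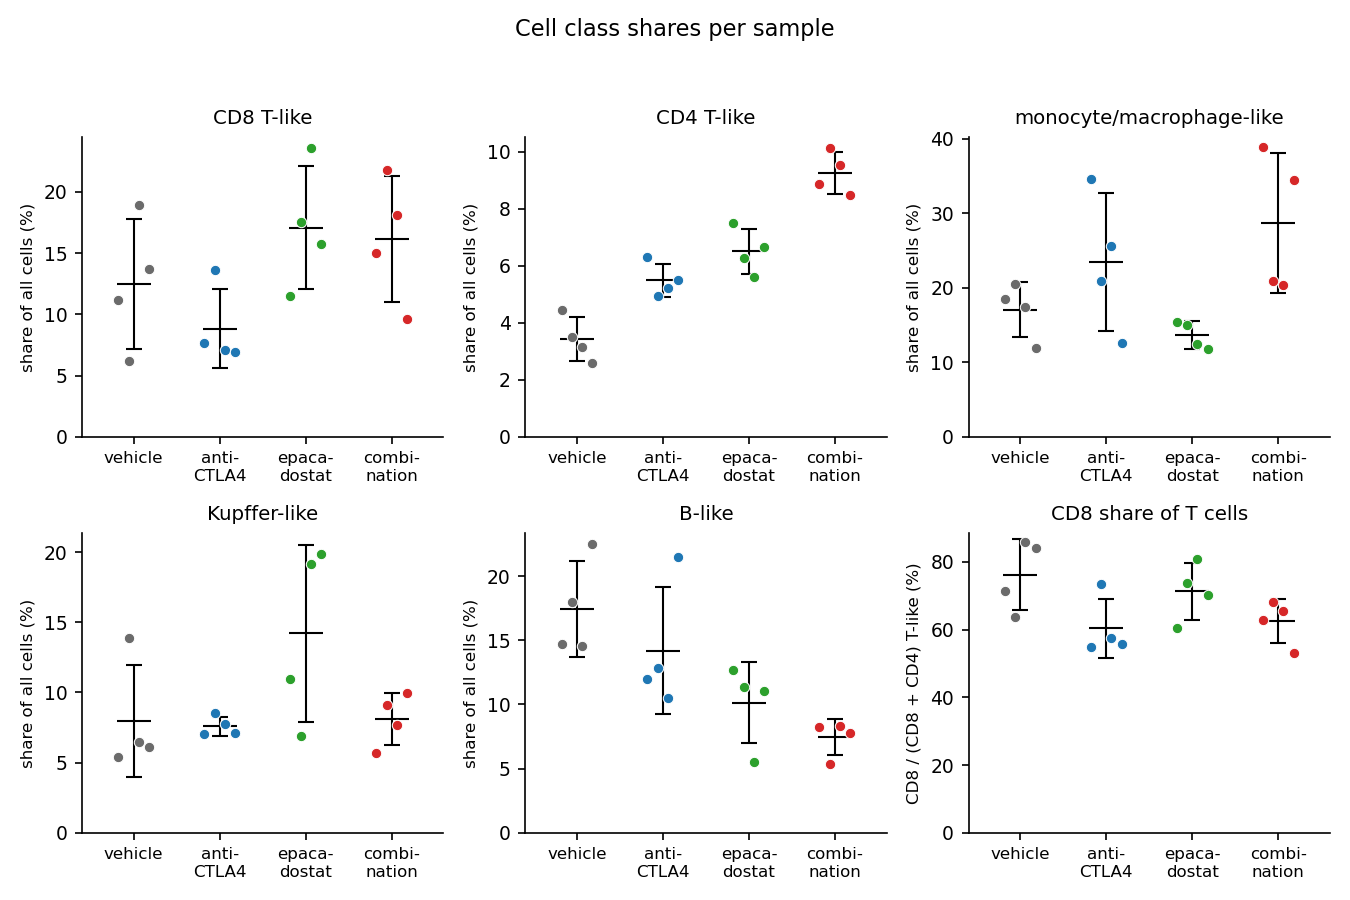
Share of all cells (y axis, %) held by 5 cell classes, and CD8 T-like cells as a share of CD8 plus CD4 T-like cells (last panel), in each of the 16 samples by group, with the mean (horizontal line) and SD (bars, n = 4). CD4 T-like cells average 3.43% with vehicle and 9.26% in the combination group, and B-like cells 17.4% and 7.42%.

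The clusters that held most of a class differed between groups, so values within a class also reflect which clusters filled it. CD8 T-like cells lay mostly in sub-clusters 0 and 4 with vehicle and in sub-clusters 0, 1, 5 and 6 in the combination group. Sub-cluster 11 held the largest part of CD4 T-like cells with vehicle and sub-cluster 8 in the combination group. For monocyte/macrophage-like cells these were clusters 3 and 2. Kupffer-like cells lay mostly in cluster 7 with vehicle or anti-CTLA4 and in cluster 4 in both groups given epacadostat. UMIs per cell were 0.210 of the sample median in cluster 7 and 1.41 times it in cluster 4. The low-UMI cluster 7 held 52.9% of the class with vehicle, 64.1% with anti-CTLA4, 30.4% with epacadostat and 43.3% in the combination group. Results in Kupffer-like cells carry this difference in cell quality, and its part in them was not tested.

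The combination against vehicle asked what both drugs together did to each cell type. In CD8 T-like cells, transcripts of perforin and granzyme B, proteins that kill target cells, rose. Prf1 (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680 on GRCm38) went from 129 ± 16.6 to 203 ± 23.2 CPM (log2 fold change 0.66 ± 0.12, SE, adjusted p = 0.00642). Gzmb went from 357 ± 77.3 to 725 ± 198 CPM (1.02 ± 0.27, adjusted p = 0.0262). Klrg1, a receptor gene of terminal effector cells (1.46 ± 0.39, adjusted p = 0.0263), and the activating receptor gene Klrk1 (1.14 ± 0.35, adjusted p = 0.0448) rose as well. In all, 1402 of 9801 genes passed (edgeR, Benjamini-Hochberg adjusted p under 0.05), 714 higher and 688 lower.

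These were the 4 of 16 cytotoxic genes that passed in CD8 T-like cells, 5 with p adjusted over the list alone. The list was called higher (camera adjusted p = 0.00592, and adjusted p = 0.469 with an estimated correlation). All 24 proliferation genes had positive changes, with a median of 1.14, and the list was called higher (camera adjusted p = 1.11e-08, and adjusted p = 0.599 with an estimated correlation). Of its members Aurkb, a kinase of cell division (1.89 ± 0.51, adjusted p = 0.032), and the tubulin gene Tubb5 (0.95 ± 0.28, adjusted p = 0.0407) passed, and 0 did with p adjusted over the list alone. Rrm2 (1.71 ± 0.58, adjusted p = 0.0647) and Kif11 (1.16 ± 0.41, adjusted p = 0.0694) did not pass. Nrgn (2.34 ± 0.67, adjusted p = 0.0385), the metallothionein gene Mt3 (2.24 ± 0.37, adjusted p = 0.00481) and Nrn1 (2.21 ± 0.54, adjusted p = 0.0225) rose by more than these.

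RNA of hepatocytes, which T cells do not make, fell in CD8 T-like cells. All 9 hepatocyte genes tested fell, 9 also with p adjusted over the list alone (camera adjusted p = 2.97e-09, and adjusted p = 0.469 with an estimated correlation). Albumin RNA (Alb, chromosome 5, 90460897 to 90476602) went from 92.1 ± 22.4 to 12.2 ± 2.50 CPM (-2.89 ± 0.45, adjusted p = 0.00563). Transthyretin (Ttr, -3.09 ± 0.54, adjusted p = 0.00709) and the apolipoprotein gene Apoa1 (-2.91 ± 0.43, adjusted p = 0.00481) fell too, as did Apoa2 (-2.55 ± 0.36), Apoc3 (-3.01 ± 0.49) and Serpina3k (-2.75 ± 0.48). Of 13 mitochondrially encoded genes 4 fell, 8 with p adjusted over the list alone (median -0.63, camera adjusted p = 0.000229, and adjusted p = 0.599 with an estimated correlation). With the mitochondrial term 12 genes passed, and 12 of the 15 called genes named here lost their call. The count was 596, 648, 563 and 520 without combination replicates 1 to 4 and 265, 2976, 288 and 451 without vehicle replicates 1 to 4, and 8 of the 15 genes (Prf1, Mt3, Ttr, Apoa1, Apoa2, Alb, Apoc3 and Serpina3k) passed in all of these fits.

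**Figure D3:**
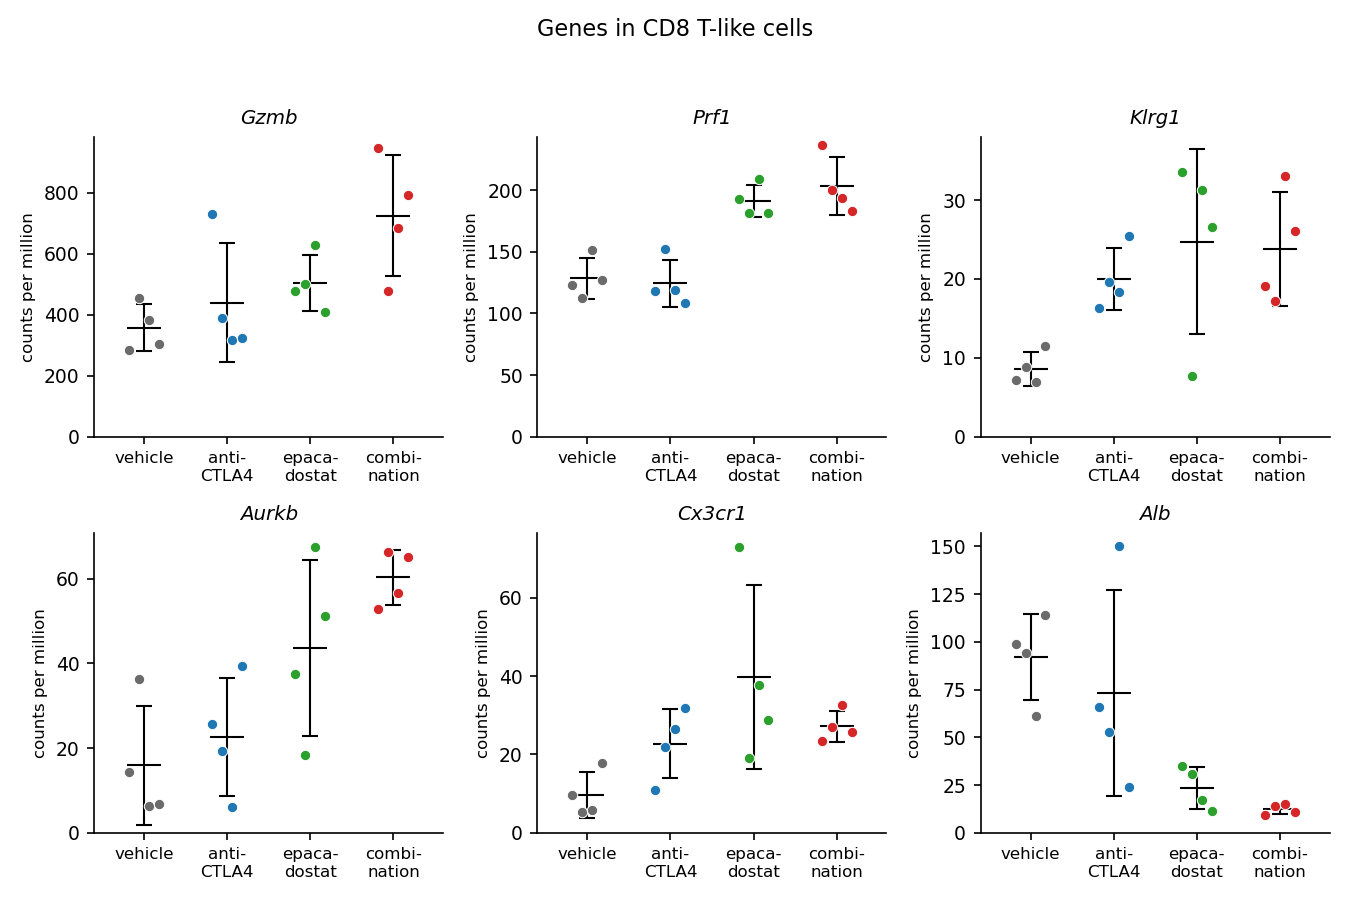
CPM (y axis) of 6 genes in CD8 T-like cells of each of the 16 samples by group, with the mean (horizontal line) and SD (bars, n = 4). Prf1 averages 129 with vehicle, 125 with anti-CTLA4, 191 with epacadostat and 203 in the combination group, and Alb 92.1, 73.2, 23.6 and 12.2.

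In CD4 T-like cells of the combination group Ccl5, a chemokine gene of effector T cells (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), went from 2898 ± 727 to 9291 ± 2630 CPM (1.68 ± 0.22, adjusted p = 0.00359). The granzyme gene Gzma went from 23.3 ± 15.6 to 274 ± 136 CPM (3.43 ± 0.71, adjusted p = 0.0444). Bach2, a repressor that holds T cells in a resting state (chromosome 4, 32238804 to 32586108), went from 28.9 ± 14.1 to 7.24 ± 1.64 CPM (-1.79 ± 0.32, adjusted p = 0.0133). In all, 96 of 8885 genes passed in edgeR, 51 higher and 45 lower. The vehicle samples held 347 to 462 CD8 plus CD4 T-like cells each and the combination samples 641 to 1251, most of them CD8 T-like. The CD4 T-like values with vehicle thus rest on fewer cells. Sub-cluster 8 held 9.32% of this class with vehicle and 24.0% in the combination group, and 31.4% of its cells had the CD8 gene Cd8b1. Sub-cluster 11 held 27.1% and 13.4%, and 12.4% of its cells had Cd8b1. Whether this mix moved the effector genes of CD4 T-like cells was not tested.

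Of 16 cytotoxic genes 5 rose in these cells, among them Gzmb (1.69 ± 0.36, adjusted p = 0.0447), Cst7 (1.15 ± 0.20, adjusted p = 0.0165) and Nkg7 (1.08 ± 0.23, adjusted p = 0.0406), and 7 were higher and 1 lower with p adjusted over the list alone (camera adjusted p = 4.14e-05, and adjusted p = 0.469 with an estimated correlation). Of 14 naive and central memory genes Bach2 and Klf3 (-1.17 ± 0.25, adjusted p = 0.0357) fell, 11 with p adjusted over the list alone (camera adjusted p = 1.58e-07, and adjusted p = 0.469 with an estimated correlation). Satb1 (-1.02 ± 0.25, adjusted p = 0.0588) and the interleukin-7 receptor gene Il7r (-1.32 ± 0.32, adjusted p = 0.0716) did not pass. All 14 checkpoint and exhaustion genes had positive changes, and 1 passed, Tigit (0.88 ± 0.19, adjusted p = 0.0388), 7 with p adjusted over the list alone (camera adjusted p = 2.47e-07, and adjusted p = 0.469 with an estimated correlation). Lag3 (1.88 ± 0.42, adjusted p = 0.0563) and Tox (0.65 ± 0.17, adjusted p = 0.0563) did not pass. The CD4 T-like class included sub-clusters 3 and 28, both led by Foxp3. Sub-cluster 3 held 14.8% of the class with vehicle and 20.8% in the combination group, and sub-cluster 28 held 6.85% and 4.80%. Whether this mix moved the checkpoint genes was not tested. Ralgps2 (-1.20 ± 0.23, adjusted p = 0.0165) and Alb (-1.97 ± 0.40, adjusted p = 0.0328) fell too. Mitochondrially encoded genes were lower (median -0.50, camera adjusted p = 1.84e-06, and adjusted p = 0.599 with an estimated correlation). The mitochondrial term left 0 genes. The count was 1, 5, 14 and 45 without combination replicates 1 to 4 and 6, 304, 2 and 10 without vehicle replicates 1 to 4, and of the 10 called genes named here Ccl5 alone passed in all of these fits.

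**Figure D4:**
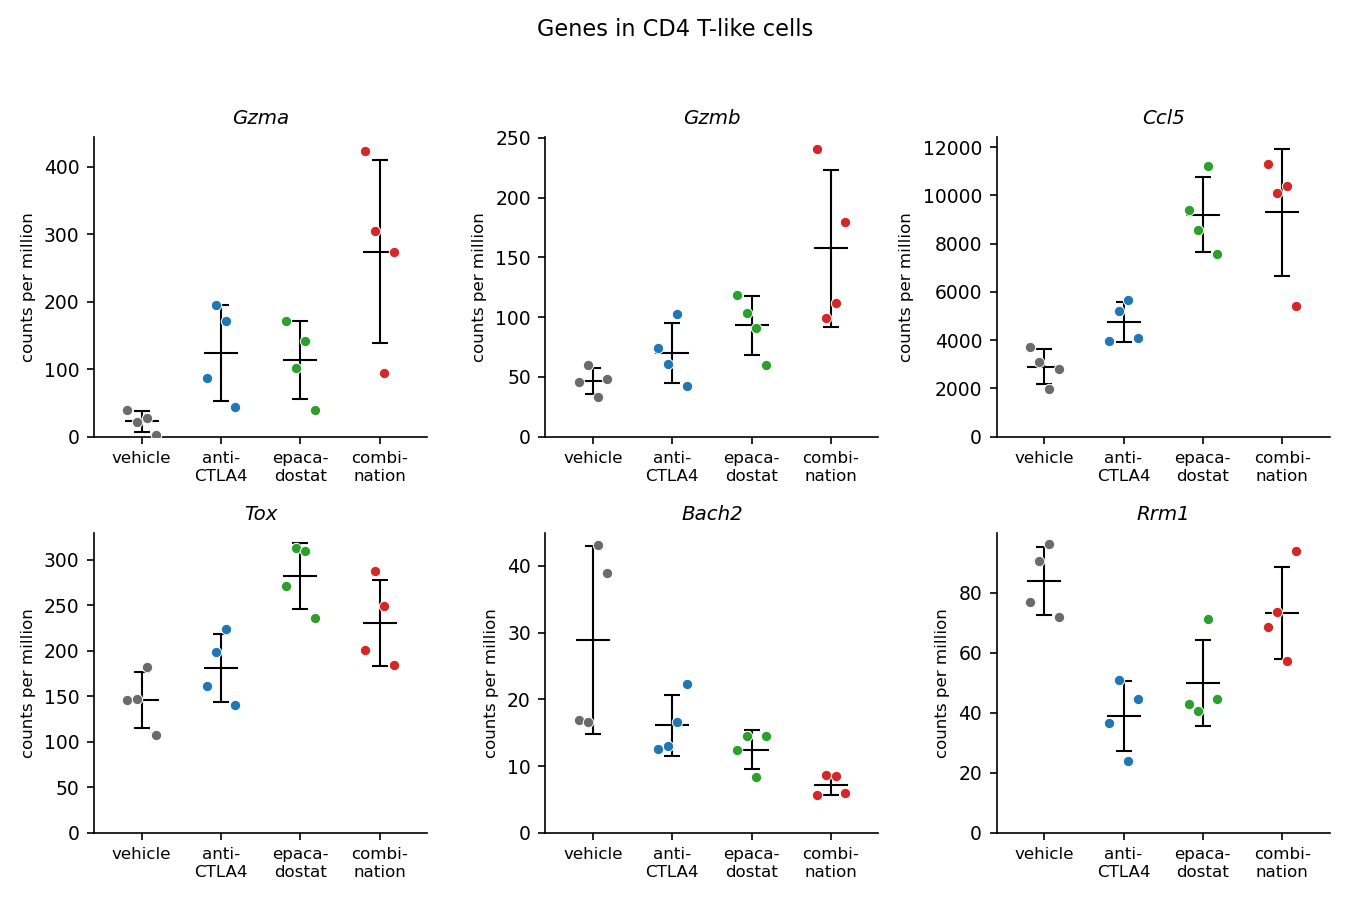
CPM (y axis) of 6 genes in CD4 T-like cells of each of the 16 samples by group, with the mean (horizontal line) and SD (bars, n = 4). Ccl5 averages 2898 with vehicle, 4746 with anti-CTLA4, 9193 with epacadostat and 9291 in the combination group, and Bach2 28.9, 16.1, 12.5 and 7.24.

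In monocyte/macrophage-like cells of the combination group C1qa, a subunit gene of the first complement component, went from 301 ± 48.6 to 810 ± 366 CPM (1.43 ± 0.35, adjusted p = 0.0394), with rises in C1qc (1.34 ± 0.37, adjusted p = 0.0496) and the receptor genes C3ar1 (1.30 ± 0.31, adjusted p = 0.0353) and C5ar1 (0.77 ± 0.20, adjusted p = 0.0414). Bcl2, which protects cells from apoptosis, fell from 48.5 ± 19.9 to 14.3 ± 2.16 CPM (-1.73 ± 0.37, adjusted p = 0.0291). Tiam2 fell (-1.95 ± 0.44, adjusted p = 0.0316) and Rhoc rose (1.32 ± 0.28, adjusted p = 0.0268). In all, 545 of 10647 genes passed in edgeR, 157 higher and 388 lower. Cluster 2, led by Saa3, held 23.5% of this class with vehicle and 48.7% in the combination group, and cluster 8 held 15.8% and 21.3%. Cluster 10, led by Ace, held 27.8% and 9.23%, and cluster 3 held 32.9% and 20.7%. The part of this mix in the changes of genes and lists in this class was not tested. The complement genes named were the 4 of 10 that passed, and 6 were higher and 1 lower with p adjusted over the list alone (camera adjusted p = 0.000543, and adjusted p = 0.469 with an estimated correlation).

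All 10 genes of MHC class II presentation had positive changes in the same cells. The protease gene Ctss passed (0.56 ± 0.14, adjusted p = 0.0371), 8 members with p adjusted over the list alone, while Lgmn (0.81 ± 0.23, adjusted p = 0.0557) and H2-Ab1 (0.81 ± 0.32, adjusted p = 0.119) did not (camera adjusted p = 0.00068, and adjusted p = 0.599 with an estimated correlation). That list gave adjusted p = 0.132 with the mitochondrial term. Of 14 lipid-associated macrophage genes, Ctsb (0.54 ± 0.12, adjusted p = 0.0291) and the lipid receptor gene Trem2 (0.54 ± 0.14, adjusted p = 0.0383) rose and the fatty acid transporter gene Cd36 fell (-1.52 ± 0.39, adjusted p = 0.0429), as many as with p adjusted over the list alone (camera adjusted p = 0.00897, and adjusted p = 0.469 with an estimated correlation). Finer clustering gave that list adjusted p = 0.931. RNA of other cells moved too. B and plasma cell genes were lower (median -2.54, camera adjusted p = 0.000688, and adjusted p = 0.599 with an estimated correlation), hepatocyte genes were lower (camera adjusted p = 0.000884, and adjusted p = 0.469 with an estimated correlation) and Kupffer cell genes higher (median 1.29, camera adjusted p = 0.00361, and adjusted p = 0.597 with an estimated correlation). The immunoglobulin gene Igkc fell (-6.12 ± 1.51, adjusted p = 0.042), which was -2.80 without vehicle replicate 4. With the mitochondrial term 0 genes passed. The count was 0, 145, 270 and 0 without combination replicates 1 to 4 and 0, 2290, 0 and 0 without vehicle replicates 1 to 4, and none of the 12 called genes named here passed in all of these fits.

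**Figure D5:**
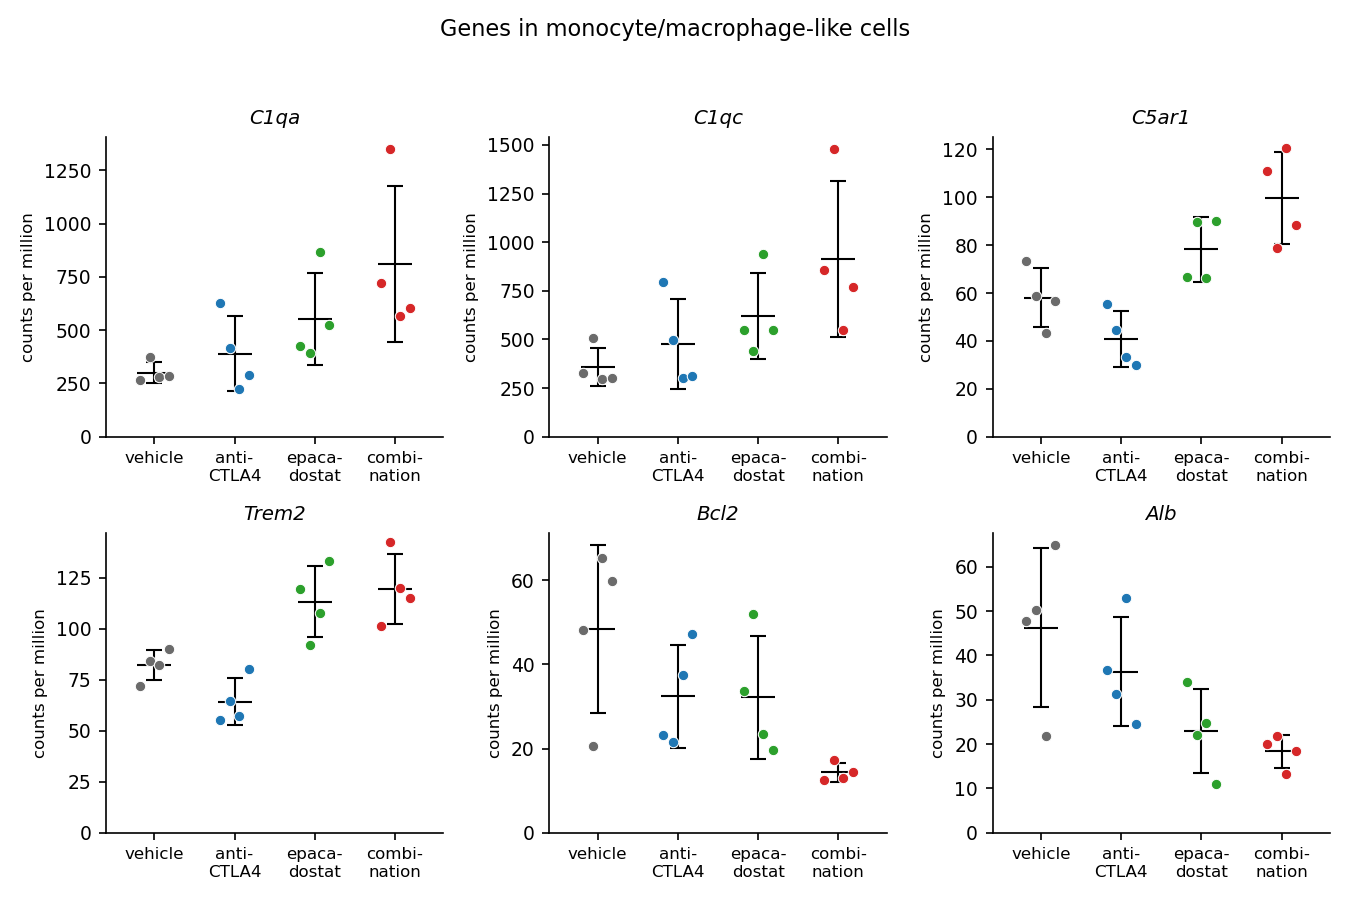
CPM (y axis) of 6 genes in monocyte/macrophage-like cells of each of the 16 samples by group, with the mean (horizontal line) and SD (bars, n = 4). C5ar1 averages 58.1 with vehicle, 40.9 with anti-CTLA4, 78.2 with epacadostat and 99.8 in the combination group, and Trem2 82.2, 64.3, 113 and 120.

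In Kupffer-like cells, the resident macrophages of the liver, interferon gamma response genes were higher as a list. Of 26 tested, 24 had positive changes (median 0.30), but 0 passed over all genes and 1 with p adjusted over the list alone (camera adjusted p = 0.000229, and adjusted p = 0.645 with an estimated correlation). Irf8 (0.60 ± 0.16, adjusted p = 0.21) and the chemokine gene Cxcl9 (1.21 ± 0.46, adjusted p = 0.371) had the smallest p. Over all genes edgeR called 0 of 8848, with 912 at an unadjusted p under 0.05 and 36 called by DESeq2. The count was 28 without vehicle replicate 2 and 1 without combination replicate 4. With the mitochondrial term the list turned lower (adjusted p = 0.62).

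Anti-CTLA4 against vehicle asked what the antibody did without epacadostat. Proliferation genes were lower as a list in CD4 T-like cells, where all 24 had negative changes (median -0.81, camera adjusted p = 4.3e-12, and adjusted p = 0.562 with an estimated correlation) and 5 passed with p adjusted over the list alone. Pcna, the sliding clamp gene of DNA replication, was at 177 ± 30.3 CPM with vehicle and 101 ± 24.4 with anti-CTLA4 (-0.80 ± 0.19, adjusted p = 0.15), and Tyms (-0.94 ± 0.29, adjusted p = 0.278) and Mcm3 (-0.82 ± 0.26, adjusted p = 0.283) did not pass either. No single gene passed in any of the 4 classes (edgeR, 0 in each). At an unadjusted p under 0.05 there were 588 in CD8 T-like, 900 in CD4 T-like, 588 in monocyte/macrophage-like and 579 in Kupffer-like cells, and DESeq2 called 0, 18, 0 and 0.

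The cytotoxic list was called higher with anti-CTLA4 in CD8 T-like cells (14 of 16 positive, camera adjusted p = 0.000985, and adjusted p = 0.562 with an estimated correlation), with 0 members past adjustment over the list alone. Ifng, the interferon gamma gene, was at 39.8 ± 16.3 CPM with vehicle and 153 ± 168 with anti-CTLA4 (1.98 ± 0.60, adjusted p = 0.783). In monocyte/macrophage-like cells the type I interferon list was called higher (26 of 29 positive, camera adjusted p = 0.000277, and adjusted p = 0.587 with an estimated correlation), with 0 members past adjustment over the list alone, and gave adjusted p = 0.135 without anti-CTLA4 replicate 1. Its leading members were Oas1a (0.40 ± 0.13, adjusted p = 0.86) and Irf7 (0.56 ± 0.20, adjusted p = 0.86). Genes induced by tissue dissociation were higher in the same cells (13 of 16 positive, camera adjusted p = 0.000127, and adjusted p = 0.562 with an estimated correlation), 6 of them with p adjusted over the list alone, with Fos at 330 ± 61.9 and 659 ± 168 CPM (1.00 ± 0.29, adjusted p = 0.86). The mitochondrial term also left 0 genes in each class. In CD4 T-like cells, 77 genes passed without anti-CTLA4 replicate 2, 15 without anti-CTLA4 replicate 4 and 5 without vehicle replicate 3.

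Epacadostat against vehicle asked the same of the IDO1 inhibitor. Klrc1, an NK cell receptor gene also used by effector T cells, rose in CD8 T-like cells from 26.9 ± 19.2 to 161 ± 73.2 CPM (2.59 ± 0.47, adjusted p = 0.0283), and the galectin-3 gene Lgals3 from 52.6 ± 20.7 to 283 ± 154 CPM (2.42 ± 0.40, adjusted p = 0.0199). The chemokine receptor gene Cx3cr1 rose too (2.01 ± 0.46, adjusted p = 0.0458). In all, 145 genes passed in edgeR, 93 higher and 52 lower. A fit of only these 2 groups gave 3 genes, and 28 passed without anti-CTLA4 replicate 4 and epacadostat replicate 3, and the 8 genes called and named for this comparison lost their call in both.

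Of 16 cytotoxic genes, Prf1 (0.57 ± 0.12, adjusted p = 0.032) and Klrk1 (1.78 ± 0.35, adjusted p = 0.0336) rose in CD8 T-like cells with epacadostat, 4 with p adjusted over the list alone (camera adjusted p = 0.00573, and adjusted p = 0.507 with an estimated correlation), and Klrg1 (1.53 ± 0.39, adjusted p = 0.0618) did not pass. All 24 proliferation genes had positive changes (median 0.73, camera adjusted p = 1.63e-06, and adjusted p = 0.676 with an estimated correlation). None passed, over all genes or over the list alone, and Aurkb had the smallest p (1.47 ± 0.52, adjusted p = 0.139). Hepatocyte RNA was lower, 4 of 9 genes past the threshold (camera adjusted p = 1.32e-07, and adjusted p = 0.507 with an estimated correlation), with Ttr (-2.54 ± 0.55, adjusted p = 0.0401), Apoa1 (-2.10 ± 0.42, adjusted p = 0.0283) and Alb (-2.04 ± 0.44, adjusted p = 0.0458) among them. The mitochondrial term left 58 genes. The count was 22, 470, 3 and 5 without epacadostat replicates 1 to 4 and 4, 1587, 8 and 23 without vehicle replicates 1 to 4, and none of the 8 called genes named here passed in all of these fits.

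Epacadostat raised, in CD4 T-like cells, Ccl5 from 2898 ± 727 to 9193 ± 1551 CPM (1.66 ± 0.22, adjusted p = 0.00409), and 3 of 14 checkpoint and exhaustion genes rose. These were Tox, a transcription factor gene of exhausted cells (146 ± 30.4 to 282 ± 36.6 CPM, 0.94 ± 0.17, adjusted p = 0.0135), the inhibitory receptor gene Tigit (234 ± 66.2 to 518 ± 58.1 CPM, 1.15 ± 0.19, adjusted p = 0.0144) and Entpd1 (0.82 ± 0.20, adjusted p = 0.047). Lag3 did not pass (1.66 ± 0.42, adjusted p = 0.0895). With p adjusted over the list alone 6 passed (camera adjusted p = 2.75e-07, and adjusted p = 0.507 with an estimated correlation). Sub-cluster 3, led by Foxp3, held 14.8% of CD4 T-like cells with vehicle and 25.1% with epacadostat. Sub-cluster 28, also led by Foxp3, held 6.85% and 5.20%. These genes may thus reflect the mix of cells, which was not tested. In all, 73 genes passed in edgeR, 51 higher and 22 lower. Sub-cluster 8, with Cd8b1 in 31.4% of its cells, held 9.32% of CD4 T-like cells with vehicle and 24.2% with epacadostat. Its part in the rise of Ccl5 was not tested. Agpat4 (1.28 ± 0.22, adjusted p = 0.00812) and Epcam (1.46 ± 0.35, adjusted p = 0.0489) rose as well. The cell division genes Blm (-1.42 ± 0.32, adjusted p = 0.0354) and Kifc1 (-1.12 ± 0.21, adjusted p = 0.0144) fell, as did Rnf19b (-1.09 ± 0.27, adjusted p = 0.0489). With the mitochondrial term 75 genes passed. The count was 23, 37, 20 and 18 without epacadostat replicates 1 to 4 and 1, 91, 30 and 26 without vehicle replicates 1 to 4, and of the 9 called genes named here Ccl5 alone passed in all of these fits.

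Proliferation genes were lower as a list in Kupffer-like cells with epacadostat. All 22 had negative changes (median -1.67, camera adjusted p = 2.11e-13, and adjusted p = 0.507 with an estimated correlation), and 15 passed with p adjusted over the list alone. Over all genes 1 passed, Mcm2, a helicase gene of DNA replication (-2.22 ± 0.37, adjusted p = 0.0247), named after its values were seen. Mcm6 (-1.61 ± 0.32, adjusted p = 0.0915) and Mcm3 (-1.03 ± 0.21, adjusted p = 0.105) did not. Of 27 type I interferon genes 25 had negative changes (median -0.52, camera adjusted p = 4.18e-07, and adjusted p = 0.507 with an estimated correlation), 3 with p adjusted over the list alone, and Ifi44 (-0.96 ± 0.22, adjusted p = 0.13) and Ifit3 (-1.13 ± 0.25, adjusted p = 0.145) had the smallest p. In Kupffer-like cells 22 genes passed without epacadostat replicate 2, 2 without epacadostat replicate 3, and 0 without epacadostat replicate 1 or 4 or vehicle replicate 2 or 3. In monocyte/macrophage-like cells edgeR called 0 of 10647 genes, with 985 at an unadjusted p under 0.05 and 24 by DESeq2, and 1 gene passed without vehicle replicate 2.

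The combination against anti-CTLA4 asked what epacadostat added to the antibody. The rises named by size in CD8 T-like cells were Shcbp1 (2.12 ± 0.47, adjusted p = 0.0392) and the histone genes Hist1h3c (2.04 ± 0.45, adjusted p = 0.0369) and Hist1h2bj (2.01 ± 0.40, adjusted p = 0.0309). Histone genes have near-identical copies, so their counts are uncertain. H2-Ab1, an MHC class II gene that antigen-presenting cells express at high levels, went from 151 ± 21.0 to 57.4 ± 10.8 CPM (-1.39 ± 0.28, adjusted p = 0.0369). In all, 245 genes passed in edgeR, 126 higher and 119 lower.

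All 24 proliferation genes had positive changes in CD8 T-like cells (median 1.47, camera adjusted p = 3.25e-13, and adjusted p = 0.467 with an estimated correlation). None passed over all genes and 23 with p adjusted over the list alone. Top2a, the topoisomerase gene of dividing cells, was at 118 ± 47.6 CPM with anti-CTLA4 and 350 ± 26.7 in the combination group (1.57 ± 0.46, adjusted p = 0.0724). Of 10 MHC class II genes H2-Ab1, H2-Eb1 (-1.29 ± 0.24, adjusted p = 0.0279), Cd74 (-1.26 ± 0.29, adjusted p = 0.0431) and H2-Aa (-1.26 ± 0.31, adjusted p = 0.049) fell, 8 with p adjusted over the list alone (camera adjusted p = 3.75e-06, and adjusted p = 0.385 with an estimated correlation). Maf, a transcription factor gene, fell as well (-1.53 ± 0.37, adjusted p = 0.049). RNA of other cells was lower with them, with 5 of 9 hepatocyte genes past the threshold (camera adjusted p = 4.74e-09, and adjusted p = 0.383 with an estimated correlation), led by Alb (-2.54 ± 0.46, adjusted p = 0.0279), and lower Kupffer cell RNA (camera adjusted p = 0.000378, and adjusted p = 0.425 with an estimated correlation). Under the mitochondrial term 282 genes passed. The count was 4, 10, 9 and 4 without combination replicates 1 to 4 and 3, 44, 0 and 1234 without anti-CTLA4 replicates 1 to 4, and none of the 9 called genes named here passed in all of these fits.

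The receptor gene Cd160 rose in CD4 T-like cells from 20.7 ± 9.74 to 68.4 ± 10.6 CPM (1.74 ± 0.33, adjusted p = 0.031), with the mitotic gene Ckap2l (1.74 ± 0.38, adjusted p = 0.041) and Dapk2 (1.15 ± 0.24, adjusted p = 0.031). Nebl (-1.52 ± 0.29, adjusted p = 0.0275), the cytokine signalling suppressor gene Socs2 (-1.49 ± 0.29, adjusted p = 0.031) and the clock gene Nr1d2 (-1.42 ± 0.32, adjusted p = 0.0381) fell. In all, 76 genes passed in edgeR, 30 higher and 46 lower. All 24 proliferation genes had positive changes (median 0.73, camera adjusted p = 7.5e-12, and adjusted p = 0.467 with an estimated correlation), 4 with p adjusted over the list alone, and Aurkb did not pass over all genes (1.26 ± 0.35, adjusted p = 0.0945). All 14 naive and central memory genes had negative changes (median -0.83, camera adjusted p = 1.35e-05, and adjusted p = 0.485 with an estimated correlation), 3 with p adjusted over the list alone, and Klf3 (-0.96 ± 0.24, adjusted p = 0.0645) and Satb1 (-0.88 ± 0.24, adjusted p = 0.0773) did not pass. Sub-clusters 11 and 31, both with Tcf7 among their leading genes, held 23.2% and 5.70% of this class with anti-CTLA4. In the combination group they held 13.4% and 2.63%. The naive and central memory genes may thus reflect the mix of cells, which was not tested. With the mitochondrial term 90 genes passed. The count was 9, 0, 3 and 13 without combination replicates 1 to 4 and 20, 144, 3 and 450 without anti-CTLA4 replicates 1 to 4, and none of the 6 called genes named here passed in all of these fits.

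Monocyte/macrophage-like cells showed 3 raised genes when epacadostat was added to anti-CTLA4. The complement receptor gene C5ar1 (ENSMUSG00000049130, chromosome 7, 16246743 to 16259540) rose from 40.9 ± 11.6 to 99.8 ± 19.3 CPM (1.25 ± 0.20, adjusted p = 0.0457). Ecm1 (1.19 ± 0.17, adjusted p = 0.0264) and Trem2 (0.91 ± 0.14, adjusted p = 0.0264) rose with it. At an unadjusted p under 0.05 there were 1520 genes, and DESeq2 called 196. C5ar1 was the 1 of 10 complement genes to pass, with 5 higher and 1 lower with p adjusted over the list alone (camera adjusted p = 0.000279, and adjusted p = 0.425 with an estimated correlation), and C3ar1 (0.92 ± 0.30, adjusted p = 0.194) and C1qa (1.05 ± 0.35, adjusted p = 0.207) did not. Trem2 was the 1 of 14 lipid-associated macrophage genes, 2 with p adjusted over the list alone (camera adjusted p = 4.92e-05, and adjusted p = 0.347 with an estimated correlation), and Spp1 (2.09 ± 0.74, adjusted p = 0.23) did not pass. Finer clustering gave that list adjusted p = 0.326. Dissociation genes were lower (15 of 16 negative, median -0.92, camera adjusted p = 5.26e-09, and adjusted p = 0.347 with an estimated correlation), 10 lower and 1 higher with p adjusted over the list alone, as in Atf3 (-1.01 ± 0.18, adjusted p = 0.0549). B and plasma cell RNA was lower too (median -2.13, camera adjusted p = 5.49e-05, and adjusted p = 0.467 with an estimated correlation). Under the mitochondrial term 9 genes passed. The count was 1, 6, 0 and 0 without combination replicates 1 to 4 and 12, 18, 0 and 5 without anti-CTLA4 replicates 1 to 4.

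Kupffer-like cells had 1 changed gene in this comparison, Sipa1l1 (1.22 ± 0.21, adjusted p = 0.0383). No gene passed without combination replicate 1 or 2 or any anti-CTLA4 replicate (edgeR, 0 in each, against 683 at an unadjusted p under 0.05 and 5 by DESeq2 with all samples), and 2 passed without combination replicate 4.

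The interaction asked whether the effect of epacadostat differed with and without anti-CTLA4. In CD4 T-like cells edgeR called 21 genes, 20 with a positive value. Rrm1, a subunit gene of the enzyme that makes deoxyribonucleotides (ENSMUSG00000030978, chromosome 7, 102441695 to 102469771), averaged 83.9 ± 11.5 CPM with vehicle, 38.9 ± 11.7 with anti-CTLA4, 49.8 ± 14.3 with epacadostat and 73.3 ± 15.4 in the combination group (1.67 ± 0.29, adjusted p = 0.0225). Kif20a, a motor protein gene of cell division (1.78 ± 0.38, adjusted p = 0.0428), and Anapc15 (1.64 ± 0.36, adjusted p = 0.0428) followed, and Ago3 had a negative value (-1.28 ± 0.26, adjusted p = 0.0336). All 24 proliferation genes had positive values (median 1.15, camera adjusted p = 2.68e-15, and adjusted p = 0.536 with an estimated correlation). Of these Pcna passed (1.30 ± 0.25, adjusted p = 0.028), 12 with p adjusted over the list alone, and Tyms did not (1.42 ± 0.38, adjusted p = 0.142). With the mitochondrial term 23 genes passed, but 0 with finer clustering or with replicate numbers as blocks. The count was 14, 10, 12 and 0 without combination replicates 1 to 4, 0, 101, 0 and 45 without anti-CTLA4 replicates 1 to 4, 18, 10, 41 and 0 without epacadostat replicates 1 to 4, and 6, 0, 6 and 22 without vehicle replicates 1 to 4, and none of the 5 called genes named here passed in all of these fits.

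In the other 3 classes edgeR called 0 genes for the interaction, with 354 in CD8 T-like, 362 in monocyte/macrophage-like and 240 in Kupffer-like cells at an unadjusted p under 0.05, and 1, 1 and 0 by DESeq2. Proliferation genes were called in CD8 T-like cells (23 of 24 positive, camera adjusted p = 0.00128, and adjusted p = 0.946 with an estimated correlation), with 0 members past adjustment over the list alone. That call was lost without anti-CTLA4 replicate 3 (adjusted p = 0.318), epacadostat replicate 2 (adjusted p = 0.0625) or vehicle replicate 2 (adjusted p = 0.552). Dissociation genes had a negative interaction in monocyte/macrophage-like cells (14 of 16 negative, median -0.77, camera adjusted p = 1.28e-07, and adjusted p = 0.536 with an estimated correlation), 4 with p adjusted over the list alone.

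The other classes were tested in the same way. In the order combination against vehicle, anti-CTLA4 against vehicle, epacadostat against vehicle, combination against anti-CTLA4 and interaction, edgeR called 11, 0, 7, 0 and 0 genes in B-like cells, with 1251, 756, 789, 632 and 361 at an unadjusted p under 0.05 and 71, 1, 19, 6 and 0 by DESeq2. In NK/ILC1-like cells it called 10, 1, 7, 3 and 0, with 1052, 574, 612, 517 and 297 unadjusted and 16, 1, 37, 7 and 0 by DESeq2. In conventional DC-like cells it called 1, 0, 1, 0 and 0, with 1613, 579, 863, 877 and 263 unadjusted and 137, 1, 3, 7 and 0 by DESeq2. In endothelial-like cells it called 0, 0, 0, 2 and 0, with 326, 217, 308, 264 and 180 unadjusted and 0, 1, 0, 3 and 0 by DESeq2. In neutrophil-like cells it called 0 in all 5, with 409, 301, 225, 353 and 195 unadjusted and 8, 0, 0, 0 and 0 by DESeq2.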

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

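Chosen only after the result was seen were the 3 patterns weighed, the tests of the labels of vehicle replicate 2, and the first test of the mitochondrial term. The tests of hepatocyte RNA, shared genes and depth and the count for the side itself were set before their results were seen.

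In 13 of 179 groups of 4 samples, the highest or lowest sample lay far from the other 3 (Dixon's test), where chance gives about 1 in 20 groups. In anti-CTLA4 replicate 2, CD8 T-like cells were 13.6% of cells (others 6.91% to 7.65%), the CD8 share of T cells was 73.4% (54.8% to 57.4%) and erythroid-like cells were 0.162% (0 in the others). Kupffer-like cells were 13.9% in vehicle replicate 2 (5.43% to 6.45%), and neutrophil-like cells 7.70% in epacadostat replicate 4 (3.03% to 3.64%). In CD8 T-like cells, Klrc1 was at 55.7 CPM in vehicle replicate 4 (16.1 to 18.8), Lgals3 at 83.5 in vehicle replicate 2 (41.3 to 43.5), Apoa1 at 10.0 in epacadostat replicate 1 (3.49 to 4.18) and Hist1h2bj at 26.7 in anti-CTLA4 replicate 4 (5.10 to 8.71). Kifc1 in CD4 T-like cells was at 17.6 CPM in epacadostat replicate 4 (18.7 to 18.8) and Rrm1 at 71.1 in epacadostat replicate 3 (40.4 to 44.7). In monocyte/macrophage-like cells, C1qc was at 507 CPM in vehicle replicate 2 (299 to 330) and Igkc at 808 in vehicle replicate 4 (12.5 to 31.9). For the interaction in CD4 T-like cells edgeR called 21 genes, among them Kif20a (1.78), Rrm1 (1.67), Anapc15 (1.64) and Ago3 (-1.28).

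The first pattern is hepatocyte RNA in CD8 T-like cells, which summed to 228 ± 53.2 CPM with vehicle and 39.0 ± 14.8 in the combination group (SD, n = 4). Sub-cluster 24 was richest in this RNA (1382 CPM, against a median of 52.0 over the others). It held 9.76% of CD8 T-like cells with vehicle and 1.43% in the combination group. Its loss as the whole cause is argued against, since without it the log2 ratio was -2.01, against -2.55 with it. Mixed cells spread over the other sub-clusters stay in that ratio, so it cannot decide on them. Free RNA in the droplets remains open and is a candidate explanation, since hepatocyte RNA was lower in 5 of 5 other classes tested for it. The log2 ratios there were -1.37 to -1.14, with -1.61 in CD4 T-like, -0.99 in monocyte/macrophage-like and -0.17 in Kupffer-like cells, all smaller falls than the -2.55. The share of free RNA also depends on the RNA of the cells themselves. Sub-cluster 6, with UMIs per cell at 1.99 times the sample median (0.719 in sub-cluster 0), held 6.19% of CD8 T-like cells with vehicle and 14.9% in the combination group. How much of the -2.55 free RNA would account for is therefore not settled. The lower free RNA may itself come from tissue handling or from the livers, which was not tested.

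The second pattern is the set of genes raised by epacadostat in CD8 T-like cells both without and with anti-CTLA4, 17 genes (expected from independent lists 1.20), with 19 lower in both (expected 0.631). The size of both lists moved widely without single samples, and other splits of the samples gave as many genes for the first, as listed below. A larger share of cells in the sub-clusters that the epacadostat-treated groups fill is argued against as the whole cause, since in 3 shared sub-clusters summed together (2759 cells) the genes kept at least 0.835 of their median change. The mix among these 3 was not held fixed, so its part was not tested. RNA from other cells is argued against, since in B-like cells their median change was at most 0.179 of that in CD8 T-like cells. A response of CD8 T cells to epacadostat is a hypothesis that stays open, found and tested on the same samples.

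The third pattern is that counts for the combination against vehicle rose without vehicle replicate 2, from 1402 to 2976 genes in CD8 T-like and from 545 to 2290 in monocyte/macrophage-like cells. It lay closer to the other vehicle samples than to the combination for 24.5% and 17.8% of these genes, which goes with a combination library under a vehicle label, but against that label it lay below all combination samples in 4 of 4 sub-clusters that these fill, and depth is argued against because the count still rose 11.7-fold after thinning. A swap with epacadostat replicate 2 cannot be told apart from its labels, since it lay at 58.6% of the way from anti-CTLA4 to combination in CD8 T-like cells, against 48.8%, and at 76.4% against 51.5% in CD4 T-like cells, as a swap needs, and exchanging the 2 gave 1602 genes against 145 for epacadostat against vehicle in CD8 T-like cells, but 0 against 73 in CD4 T-like cells, and it lay below epacadostat replicate 2 in 3 of 4 sub-clusters, by most in sub-cluster 1 (0.112% of cells against 1.84%, other vehicle samples at most 0.0824%), where each lay with its own label. A library difference along the mitochondrial sides may contribute: the mitochondrial term left 12 genes in CD8 T-like cells, and the side itself had 14 genes there (3 of 96 arrangements of the sides gave as many, the highest other 989) and 520 in monocyte/macrophage-like cells (1 of 96, the highest other 9). As few genes were left in 26 of 96 arrangements in CD8 T-like and 55 of 96 in monocyte/macrophage-like cells, so the loss of calls decides nothing, because any such term overlaps the groups with 3 of 4 vehicle and 0 of 4 combination samples on the high side, and the division may be technical or biological.

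Other splits of the same samples were counted for each comparison (35 splits of 2 groups, 100 drawn for the interaction), with the real count, the highest other and the number of splits as large, the real one included. The 45 tests were not adjusted for one another and 1 of 35 is the smallest share possible, so some may pass by chance, and a count of 1 gene is weak evidence. Chance is therefore excluded for no single count. For the combination against vehicle, no other split gave as many genes in CD8 T-like cells (1402, highest other 0, 1 split), CD4 T-like (96, highest other 8, 1 split), B-like (11, highest other 1, 1 split) and conventional DC-like cells (1, highest other 0, 1 split). Other splits gave as many in monocyte/macrophage-like (545, highest other 761, 2 splits), NK/ILC1-like (10, highest other 126, 3 splits), Kupffer-like (0, highest other 1), endothelial-like (0, highest other 1) and neutrophil-like cells (0, highest other 0), where for a count of 0 all 35 are as large. The highest split in monocyte/macrophage-like and NK/ILC1-like cells set combination replicates 1, 3 and 4 with vehicle replicate 2 against the rest.

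For anti-CTLA4 against vehicle, the real count was 0 in 8 classes, so all 35 splits were as large. The highest others were 123 in CD8 T-like, 103 in CD4 T-like, 614 in monocyte/macrophage-like, 102 in Kupffer-like, 12 in B-like, 1 in conventional DC-like, 38 in endothelial-like and 220 in neutrophil-like cells. In NK/ILC1-like cells (1, highest other 38) 8 splits were as large. In CD4 T-like, monocyte/macrophage-like, Kupffer-like, NK/ILC1-like, endothelial-like and neutrophil-like cells the highest other split was that of the mitochondrial sides, with vehicle replicate 2 beside anti-CTLA4 replicates 1 to 3, so it follows a structure of the samples.

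For epacadostat against vehicle, no other split gave as many genes in CD4 T-like (73, highest other 0, 1 split), B-like (7, highest other 2, 1 split) and NK/ILC1-like cells (7, highest other 5, 1 split). Other splits gave as many in CD8 T-like (145, highest other 1602, 3 splits), Kupffer-like (1, highest other 21, 10 splits) and conventional DC-like cells (1, highest other 1, 3 splits), and with a count of 0 in monocyte/macrophage-like (highest other 262), endothelial-like (4) and neutrophil-like cells (1). The highest split in CD8 T-like and monocyte/macrophage-like cells set epacadostat replicates 1, 3 and 4 with vehicle replicate 2, an exchange of the replicates 2. It gave 1602 genes against the real 145 in CD8 T-like cells and 262 against 0 in monocyte/macrophage-like cells, which points to a structure of the samples.

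For the combination against anti-CTLA4, no other split gave as many genes in CD8 T-like (245, highest other 1, 1 split), CD4 T-like (76, highest other 7, 1 split) and monocyte/macrophage-like cells (3, highest other 0, 1 split). Other splits gave as many in Kupffer-like (1, highest other 2, 5 splits), NK/ILC1-like (3, highest other 3, 4 splits) and endothelial-like cells (2, highest other 49, 7 splits), and with a count of 0 in B-like (highest other 4), conventional DC-like (1) and neutrophil-like cells (1). For the interaction in CD4 T-like cells (21, highest other 22), 3 of 100 splits gave as many genes, the real one included. These splits mixed the labels of all 4 groups, which also breaks up the effect of each drug, so they cannot decide on the interaction alone. In the other classes the real count was 0 and all 100 splits were as large (highest other 8 in CD8 T-like, 1960 in monocyte/macrophage-like, 72 in Kupffer-like, 14 in B-like, 10 in NK/ILC1-like, 16 in conventional DC-like, 11 in endothelial-like and 124 in neutrophil-like cells).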

How the results depend on the processing

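Chosen after the data were seen were the fits without anti-CTLA4 replicate 4 and epacadostat replicate 3 (the doubted samples), the mitochondrial term, the permutation within its sides and the leaving out of single samples for shares between 2 groups. Other alternatives were fixed before the data were examined. The alternatives were compared for 157 values of named genes, which leave out Pdcd1, Ctla4, Ido1, Ido2, Tdo2, Mcm2 and the genes of the other classes. None of these values changed direction under any alternative, and the cause of the moves below was not tested. Of the 157 values, 78 were called. Of these calls 2 were lost with RLE size factors, 2 with DESeq2 (29 others gained one), 14 without the doubted samples (11 gained), 15 with doublets kept, 20 with a mitochondrial limit of 5%, 23 without the low-count filter, 34 with finer clustering (156 values) and 41 (52.6%) with the mitochondrial term. Small changes were often missed, since in simulated counts 21.2% to 35.8% of genes changed 1.5-fold were recovered in the 4 classes.

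Counts of genes moved by over 1.5 times for the following. In CD8 T-like cells, the combination against vehicle (1402) gave 12 with the mitochondrial term and 265 (without vehicle replicate 1) to 2976 (without vehicle replicate 2). Epacadostat against vehicle (145) gave 452 with DESeq2, 95 with doublets kept, 3 with only the 2 groups compared, 58 with the mitochondrial term, 28 without the doubted samples and 3 (without epacadostat replicate 3) to 1587 (without vehicle replicate 2). The combination against anti-CTLA4 (245) gave 718 with DESeq2, 143 with finer clustering, 842 with only the 2 groups, 1220 without the doubted samples and 0 (without anti-CTLA4 replicate 3) to 1234 (without anti-CTLA4 replicate 4). The interaction (0) gave 1 with DESeq2.

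In CD4 T-like cells, the combination against vehicle (96) gave 211 with DESeq2, 195 with finer clustering, 21 with a mitochondrial limit of 5%, 152 without the low-count filter, 147 with only the 2 groups, 0 with the mitochondrial term, 201 without the doubted samples and 1 (without combination replicate 1) to 304 (without vehicle replicate 2). Anti-CTLA4 against vehicle (0) gave 18 with DESeq2, 2 with RLE size factors, 2 with doublets kept, 15 with the 5% limit, 25 without the low-count filter, 15 without the doubted samples and 0 (without anti-CTLA4 replicate 1) to 77 (without anti-CTLA4 replicate 2). Epacadostat against vehicle (73) gave 149 with DESeq2, 177 with finer clustering, 44 with the 5% limit, 128 without the low-count filter and 1 (without vehicle replicate 1) to 91 (without vehicle replicate 2). The combination against anti-CTLA4 (76) gave 210 with DESeq2, 195 with finer clustering, 38 with the 5% limit, 179 without the low-count filter, 492 without the doubted samples and 0 (without combination replicate 2) to 450 (without anti-CTLA4 replicate 4). The interaction (21) gave 40 with DESeq2, 0 with finer clustering, 60 without the low-count filter, 83 without the doubted samples and 0 (without combination replicate 4) to 101 (without anti-CTLA4 replicate 2).

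In monocyte/macrophage-like cells, the combination against vehicle (545) gave 1110 with DESeq2, 272 without the low-count filter, 233 with only the 2 groups, 0 with the mitochondrial term, 910 without the doubted samples and 0 (without combination replicate 1) to 2290 (without vehicle replicate 2). Epacadostat against vehicle (0) gave 24 with DESeq2, 1 with only the 2 groups and 0 (without epacadostat replicate 1) to 1 (without vehicle replicate 2). The combination against anti-CTLA4 (3) gave 196 with DESeq2, 7 with doublets kept, 1 with finer clustering, 6 with the 5% limit, 9 without the low-count filter, 0 with only the 2 groups, 9 with the mitochondrial term, 9 without the doubted samples and 0 (without combination replicate 3) to 18 (without anti-CTLA4 replicate 2). The interaction (0) gave 1 with DESeq2.

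In Kupffer-like cells, the combination against vehicle (0) gave 36 with DESeq2, 3 without the low-count filter, 3 with only the 2 groups and 0 (without combination replicate 1) to 28 (without vehicle replicate 2). Epacadostat against vehicle (1) gave 9 with DESeq2, 0 with doublets kept, 2 with finer clustering, 0 with the 5% limit, 15 without the low-count filter, 0 with only the 2 groups, 4 without the doubted samples and 0 (without epacadostat replicate 1) to 22 (without epacadostat replicate 2). The combination against anti-CTLA4 (1) gave 5 with DESeq2, 0 with doublets kept, 0 with finer clustering, 0 with the 5% limit, 5 without the low-count filter, 0 with only the 2 groups, 2 with the mitochondrial term, 0 without the doubted samples and 0 (without combination replicate 1) to 2 (without combination replicate 4).

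The replicate numbers did not pair the samples. Of 24 same-numbered pairs, 4, 3, 8 and 4 had a correlation of deviations over 0.1 in CD8 T-like, CD4 T-like, monocyte/macrophage-like and Kupffer-like cells, and 5, 2, 4 and 2 of 16 samples lay closest to their own number. With the replicate block, CD8 T-like counts were 60 for epacadostat against vehicle and 20 for the combination against anti-CTLA4. CD4 T-like counts with the block were 47 for the combination against vehicle, 43 for epacadostat against vehicle, 41 for the combination against anti-CTLA4 and 0 for the interaction. Monocyte/macrophage-like counts with the block were 24 for the combination against vehicle and 9 for the combination against anti-CTLA4, and the Kupffer-like count for epacadostat against vehicle was 0. Shares under the block gave 2.41 points for CD4 T-like (exact adjusted p = 0.0508) and 10.7 points for monocyte/macrophage-like cells with anti-CTLA4 (exact adjusted p = 0.0508), both at the smallest p its arrangements allow (0.00781), which fixes that adjusted p when 2 of 13 classes reach it, so these losses say nothing about stability, and 5.96 points for CD8 T-like cells with epacadostat (exact adjusted p = 0.0339). Of the 78 calls of named genes 41 were lost under the block, and 6 other values gained one, and it changed no call of a list discussed and no other share or count by over 1.5 times.

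Lists called by camera numbered 43, 46, 36, 35 and 19 of 112 for the combination against vehicle, anti-CTLA4 against vehicle, epacadostat against vehicle, the combination against anti-CTLA4 and the interaction. An estimated correlation left 0 in each, and fry called 11, 0, 3, 4 and 0. The mitochondrial term gave 25 for the combination and 25 for anti-CTLA4 against vehicle. Without single samples, the counts ranged from 25 (without anti-CTLA4 replicate 1) to 60 (without anti-CTLA4 replicate 4) for anti-CTLA4 against vehicle, 22 (without vehicle replicate 3) to 37 (without epacadostat replicate 2) for epacadostat against vehicle and 11 (without anti-CTLA4 replicate 3) to 31 (without combination replicate 2) for the interaction. The interferon gamma list in Kupffer-like cells, combination against vehicle, turned lower with the mitochondrial term (signed log10 value -0.41, adjusted p = 0.62).

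For the effect of anti-CTLA4 on shares, B-like cells gave -4.96 points without the doubted samples (exact adjusted p = 0.00531) and -4.19 (without anti-CTLA4 replicate 4, exact adjusted p = 0.0424) to -2.13 points (without vehicle replicate 4). NK/ILC1-like cells gave -3.33 points without the doubted samples (exact adjusted p = 0.0106), a log2 change of -0.86 with edgeR on cell counts (adjusted p = 0.0405), -0.90 with limma on logit shares (adjusted p = 0.046) and -2.97 (without anti-CTLA4 replicate 4, exact adjusted p = 0.0283) to -2.12 points (without epacadostat replicate 1). Monocyte/macrophage-like cells gave 9.47 points with the 5% limit (exact adjusted p = 0.0923), 5.61 points with finer clustering (exact adjusted p = 0.103), 8.69 points within the mitochondrial sides (exact adjusted p = 0.271) and 8.85 (without anti-CTLA4 replicate 1, exact adjusted p = 0.125) to 12.5 points (without anti-CTLA4 replicate 4, exact adjusted p = 0.00531), with the call lost without 12 of 16 samples. CD4 T-like cells gave 2.55 points within the sides (exact adjusted p = 0.0542), the smallest adjusted p a single class can reach there, so this loss says nothing about stability. Neutrophil-like cells gave 0.906 (without combination replicate 3) to 1.93 points (without epacadostat replicate 4, exact adjusted p = 0.0398). The CD8 share of T cells gave -10.02 points without the doubted samples (exact p = 0.0571). For the effect of epacadostat, CD8 T-like cells gave 4.88 (without epacadostat replicate 3) to 7.04 points (without combination replicate 4), called without vehicle replicate 3 (7.03, exact adjusted p = 0.0371). Endothelial-like cells gave -2.32 (without vehicle replicate 3, exact adjusted p = 0.0464) to -1.34 points (without vehicle replicate 1). Between 2 groups, limma on logit shares called B-like (-1.39, adjusted p = 0.00854) and CD4 T-like cells (1.54, adjusted p = 0.000114) for the combination against vehicle. It also called CD4 T-like cells for epacadostat against vehicle (0.985, adjusted p = 0.00964) and the combination against anti-CTLA4 (0.811, adjusted p = 0.0438). Other share effects kept their side of the threshold under these alternatives, and doublets kept or another denominator changed none.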

Other observations

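All genes of this part were named after their values were seen, with values from edgeR.

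In B-like cells epacadostat against vehicle raised Hsp90ab1 by 0.72 (adjusted p = 0.000942), Hspd1 by 0.81, Ahsa1 by 0.73, Ahsa2 by 0.88 and Hspe1 by 0.62, which are chaperone or co-chaperone genes, and 1700030K09Rik by 0.89, and Ddx6 fell by 0.62. The rises of Ahsa1 and Hsp90ab1 were not particular to B-like cells, since Ahsa1 was also called in CD8 T-like cells (0.66, adjusted p = 0.0283) and both had positive changes in 9 of 9 classes. Hspd1 was higher in 7 of 9 classes and Hspe1 in 8 of 9, and Ahsa2 was not compared across classes. Hsp90ab1, Hspd1 and Hspe1 were each called in 1 class only, the B-like cells. Chaperones as a set were not tested. In conventional DC-like cells the only gene called was Hspa8, in epacadostat against vehicle (0.77, adjusted p = 0.00596), where chance could not be excluded (3 splits of the samples, the real one included, had as many calls), and in the combination against vehicle (0.70, adjusted p = 0.0214). Its rise was not particular to these cells. Hspa8 had positive changes in 9 of 9 classes in both comparisons, and was called in 2 and 3 classes. It was also higher in 9 of 9 classes for anti-CTLA4 against vehicle and for the combination against anti-CTLA4, with 0 calls in each.

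Chance could not be excluded either for 4 sets of calls that follow. In NK/ILC1-like cells, the calls for the combination against vehicle (3 splits had as many) included higher Batf3 (2.76, adjusted p = 0.00627), Batf (1.13, adjusted p = 0.00627), Bcl3 (1.32, adjusted p = 0.0131) and Traf1 (0.75), and lower RNA of the hepatocyte gene Alb (-1.79, adjusted p = 0.0172). Zfp36 was called higher in these cells with anti-CTLA4 against vehicle (1.02, adjusted p = 0.01, 8 splits) and lower in the combination against anti-CTLA4 (-1.16, adjusted p = 0.00319, 4 splits), with Ppp1r15a (-1.88) and Vps37b (-0.65). In endothelial-like cells, Shroom2 (1.79, adjusted p = 0.00125) and Sult1a1 (1.34, adjusted p = 0.0178) were called higher in the combination against anti-CTLA4 (7 splits).

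In NK/ILC1-like cells, epacadostat against vehicle lowered the cell division genes Ncapg2 (-3.41), Aspm (-3.22), Hmmr (-3.77) and Lig1 (-1.58), and raised Clec2i (0.85). In B-like cells the combination against vehicle raised the DNA sensor gene Tlr9 (0.77) and Hmga1 (0.66) and lowered Trim25 (-0.83), Rabgap1l (-0.63), Sla (-0.61) and Txnip (-0.48).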
